A study of Mus musculus with 22 samples.

How the data were processed

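Liver RNA of 22 mice was measured, 1 array per mouse, on 2-colour Agilent mouse gene expression arrays of design 014868. Per the labels, each liver RNA was labelled with Cy3 and hybridised together with a common mouse reference RNA from Stratagene labelled with Cy5, so no dye was swapped. The samples fall into 6 groups by the genotype and treatment in their labels: 4 wild-type and 4 knockout newborns, 4 control and 4 knockout fasted adults, and 3 control and 3 knockout fed adults. The labels call the samples of a group biological replicates.

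Per the file headers, the scans were quantified with Agilent Feature Extraction 10.5.1.1 under the protocol GE2_105_Dec08, with probe positions on build mm9. The submitters' processing notes name Feature Extraction 8.5.1.1 instead, and which of these made the deposited values stays open. Per the file headers, the values in each array file are spot intensity values, the median brightness of a spot and of its local background in each channel without normalization, and processed intensity values that Feature Extraction had background-subtracted and dye-normalized. The files also hold the deposited log10 ratio of reference over sample that Feature Extraction computed from the processed signals. The table of all samples that the authors deposited holds log10 ratios too. On each of the 22 arrays its largest difference from the log ratio in the array file was 0, so its scale, direction and lack of a step between arrays are known. Its column median was 0 on all newborn and fasted arrays. On the fed arrays it was 0.0474, 0.0405 and 0.0336 for control 1, 2 and 3 and 0.0183, 0.0442 and 0.0666 for knockout 1, 2 and 3.

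Ratios were recomputed from the median spot intensities, because the adult files hold no mean signals. Background was corrected with normexp at an offset of 50, each array was normalized with loess in which control spots had no weight, and the sign was turned so that values are log2 of liver over reference. No step between arrays was applied. Spots that Feature Extraction marked as non-uniform or as population outliers in either channel were set to missing, control spots were left out, and spots of one probe were averaged. The design fixed before the data were examined said only normexp with that offset. On newborn wild type 3, newborn knockout 1 and fasted control 1 and 2, between 2 and 7 spots lay below their own local background, which Feature Extraction marked as an outlier, with a lowest difference of -590541 intensity units on fasted control 1. With these values kept, normexp gave median log2 sample signals of 9.83, 9.92, 11.43 and 10.46 on these arrays. Local backgrounds so marked were therefore replaced by the median background of the array, which gave 7.20, 7.14, 6.93 and 6.75. This step was chosen after the counts of changed genes with the values kept had been seen, so 2 versions of the measurement were fitted. The counts of both are given with each comparison of 2 groups.

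Of 41174 probes that are not controls, 32909 were named through accessions, symbols or synonyms in a RefSeq table of assembly GRCm38.p6, used for names only, and 8265 kept the name in the file. Coordinates are those of the array files on mm9. A probe was tested where its sample channel was well above background on at least 4 newborn or 3 adult arrays, and 1 probe per gene was kept, the brightest. This left 17153 genes in the newborn fit and 17162 in the adult fit.

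Groups were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05 on the adjusted p. Files were read with data.table in version 1.17.8, and figures were drawn with matplotlib 3.10.9 and NumPy 2.4.6 under Python 3.11.15. The newborn fit held the 8 newborn arrays with 6 residual degrees of freedom. The adult fit held the 14 adult arrays with 1 mean for each of 4 groups and 10 residual degrees of freedom. It gave the knockout change in each feeding state, the fasting change in each genotype, and their interaction. Fixed gene lists, 31 in number, covered liver pathways, liver zones, sex-biased genes and markers of other cell types. The 30 lists with at least 5 tested genes were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists. Of the list members, 7 matched no probe name and were not analysed here.

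The samples and groups, tests, gene lists, naming rule and most alternatives were set before the data were examined. By that rule Tcf7l2 came first. From each comparison it took up to 10 genes with the largest rise and 10 with the largest fall, if they passed the threshold, had a gene symbol, had separate ranges in the groups compared and were well above background on every array of a group. From each list it took up to 4 members with the smallest adjusted p, and where fewer than 10 genes rose or fell it took 5 genes that did not pass. Only part of the genes this rule takes is named in the text. Where a probe was not well above background on any array of a group, the fold is given as a lower bound. That bound sets the mean of the bright group against the mean of the dim one, in which each array counts at no less than its lowest signal well above background, per channel after loess and Aquantile normalization. Where such a bound came out above the measured fold, no fold is given. Such bounds are open to dye bias, since no dyes were swapped. They hold for the main processing only. For Sp5, Lgr5, Cyp2c38, Slc1a2, Vldlr, Tie1 and Akr1d1 some alternatives gave changes smaller than the bound.

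The number of arrays and the signal over background limit the precision. The share of sample-channel spots well above background was 50.2% to 64.4% on newborn arrays, 50.2% to 62.0% on fasted arrays and 22.8% to 31.2% on fed arrays, where negative control spots varied more. Their SD was 42.0 to 67.7 intensity units on fed arrays, against 2.81 to 11.1 on fasted and 6.54 to 10.3 on newborn arrays. Leaving control spots aside, no spot was saturated in the sample channel, and saturation of the reference channel was not counted. Within groups, arrays correlated at 0.922 to 0.979 over probes, and no pair held identical values. In data simulated from the real arrays, changes of 2 on the log2 scale were recovered for 96% of changed genes in the newborn comparison of 17153 genes. Among the 17162 adult genes they were recovered for 97% in the fasted knockout, 93% in the fed knockout, 96% in the fasting comparison of controls and 97% in that of knockouts. Changes of 1 were recovered for 70%, 84%, 73%, 77% and 73%, in the same order, with 11, 6, 14, 8 and 11 false calls. The simulation drew independent noise for each gene with the spread of all arrays of the fit, and held no slide or scan-day effect. Recovery in the real data, above all on the fed arrays, may therefore be lower.

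The arrays lay on 6 slides and were scanned on 3 days. Wild-type and knockout newborns each filled a slide of their own, and fed arrays shared no slide and no scan day with fasted arrays. Slides 3 and 4 each held 2 fasted controls and 2 fasted knockouts. Slide 5 held 1 fed control and 2 fed knockouts, and slide 6 held 2 fed controls and 1 fed knockout.

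The alternatives tried were the processed signals of Feature Extraction, the deposited table, no background subtraction, Aquantile normalization between arrays, median centring in place of loess and the sample channel alone with quantile normalization. Others were no filter on dim probes, a filter on both channels of every array, the mean of the probes of a gene, array weights, eBayes with trend and robust settings, slide as a block and each slide alone. The remaining ones were the replicate number as a block, only the compared groups in the fit, the Xist ratio as a covariate, a condition of at least 2-fold, and each array left out in turn. Added after seeing the data were the local backgrounds kept as they were, a filter on the fed arrays alone, and 3 newborn arrays left out.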

Results

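Gene expression was measured in the livers of mice labelled wild type or control and of mice labelled knockout for Tcf7l2, a transcription factor that acts with beta-catenin in Wnt signalling, around birth and in the adult. The newborn set held 4 wild-type and 4 Tcf7l2 knockout C57BL/6 pups, given 50 ul of 10% glucose under the skin, with livers taken 5 h after birth. The adult set held mice with loxP-flanked Tcf7l2 treated with tamoxifen at 3 weeks of age, without (control) or with (knockout) a tamoxifen-activated Cre recombinase, named SA-CreERT2 in the labels. After 1 to 2 months the adults were fasted for 24 h (4 controls, 4 knockouts) or fed (3 controls, 3 knockouts). Values are log2 ratios of liver over a common reference RNA. On newborn arrays 50.2% to 64.4% of liver-channel spots were well above background, on fasted arrays 50.2% to 62.0% and on fed arrays 22.8% to 31.2%, so low signals were measured least well in fed livers.

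Tcf7l2 itself was read by 3 probes on chromosome 19 of build mm9, at 55982975 to 55983034, 56006460 to 56006519 and 56007586 to 56007645. The brightest, probe A_52_P566741 at the last of these positions, gave log2 ratios of -1.28, -0.83, -0.70 and -0.32 in newborn wild types 1 to 4 and of -1.85, -1.57, -1.58 and -1.63 in newborn knockouts 1 to 4. All 4 knockouts lay below all 4 wild types, with a change of -0.87 ± 0.19 (SE) that did not pass (limma adjusted p = 0.0564). In adults the same probe read -0.13, 0.09, 0.03 and -0.10 in fasted controls and 0.63, -0.15, 0.22 and 0.57 in fasted knockouts. It read -0.37, -0.06 and -0.64 in fed controls and 0.01, -0.35 and -0.13 in fed knockouts. The adult knockout changes were 0.35 ± 0.17 fasted (adjusted p = 0.490) and 0.21 ± 0.20 fed (adjusted p = 0.999), neither of them a fall. The probes at the first and second positions changed by 0.08 and -0.09 in newborns, with the second well above background on no newborn array, by -0.07 and 0.02 in fasted adults and by 0.38 and -0.11 in fed adults, where neither was well above background. The labels do not say which part of the gene was removed, and a probe outside it checks nothing. The adult groups are therefore called control and knockout by their labels alone, and every adult direction below rests on those labels.

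In livers of newborn knockouts, 4 of 20 tested genes of the hepatocytes around the central vein were lower than in wild types, though as a list they did not pass with an estimated correlation (adjusted p = 0.404). Rhbg, an ammonia transporter of these cells, fell from 3.96 ± 0.58 (SD, n = 4) to 0.93 ± 0.25 (SD, n = 4), a log2 change of -3.03 ± 0.27 (SE, adjusted p = 0.00185) and 8.16-fold. The cytochrome P450 gene Cyp2c37 fell by 1.63 ± 0.30 (adjusted p = 0.0355), the bile acid and drug uptake transporter gene Slco1b2 by 1.06 ± 0.20 (adjusted p = 0.0357) and Gulo, which encodes the last enzyme of vitamin C synthesis, by 0.63 ± 0.13 (adjusted p = 0.0471). Aqp9, the glycerol channel of hepatocytes, fell by 1.32 ± 0.16 and Slc17a2 by 1.42 ± 0.13. The largest rise was that of Stc1, the gene of the hormone stanniocalcin, at 2.63 ± 0.22 (adjusted p = 0.00185), from 1.74 ± 0.49 to 4.37 ± 0.14 (SD, n = 4 each).

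Among 20 tested pericentral hepatocyte genes 4 fell and none rose, while 9 fell and 3 rose when adjusted over the list alone. As a list they were lower by camera (adjusted p = 0.000183), but not with an estimated correlation (adjusted p = 0.404). Periportal hepatocyte genes, on the opposite side of the lobule, also had a median below 0, at -0.21. Of 20 tested none passed over all genes, and 2 fell and 1 rose when adjusted over the list alone (camera adjusted p = 0.0379, and adjusted p = 0.549 with an estimated correlation). None of 15 tested Wnt target genes passed over all genes or when adjusted over the list alone (camera adjusted p = 0.326). Of 19 genes of bile acid synthesis and transport 2 fell, Slco1b2 and Hsd3b7 (-0.69 ± 0.13), and 4 when adjusted over the list alone (camera adjusted p = 0.000183, and adjusted p = 0.404 with an estimated correlation). None of 33 genes of fatty acid oxidation and ketogenesis passed in limma over all genes, 4 fell when adjusted over the list alone, and 30 of 33 changes lay below 0 with a median of -0.39. Their camera adjusted p was 1.10e-07 and rose to 0.404 with an estimated correlation. This list was also lower in the knockouts of fasted and fed adults, with medians of -0.13 and -0.09 (camera adjusted p = 0.000470 and 0.000753, and adjusted p = 0.653 and 0.557 with an estimated correlation). In fasted adults the medians were -0.13 on slide 3 and -0.17 on slide 4. In fed adults they were 0.05 on slide 5 and -0.15 on slide 6, so the fed direction turned between slides.

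Of 17 markers of Kupffer cells, the macrophages of the liver, 2 fell, Marco (-1.34 ± 0.17, adjusted p = 0.00796) and Csf1r (-0.70 ± 0.14, adjusted p = 0.0486), and 6 when adjusted over the list alone. Fcna, which macrophages express, fell by 1.37 ± 0.28. Their camera adjusted p was 3.24e-05, and adjusted p = 0.404 with an estimated correlation. None of 19 erythroid markers passed over all genes or when adjusted over the list alone, and 18 of them lay below 0 (camera adjusted p = 0.00169, and adjusted p = 0.521 with an estimated correlation). No endothelial or stellate cell marker passed over all genes, and 3 of 18 and 3 of 19 fell when adjusted over the list alone, with 1 stellate marker higher (camera adjusted p = 0.0379 and 0.0450, and adjusted p = 0.636 for each with an estimated correlation). The rises came largely from genes with little signal: 123 of the 198 were among the 4289 genes with the lowest signal. They included 26 of 279 tested olfactory receptor genes and 5 of 32 vomeronasal receptor genes, families looked at only after the rises were seen, among them Olfr1434 (1.80 ± 0.23) and Vmn1r63 (1.60 ± 0.16). Gnat1, the rod transducin gene, rose by 1.62 ± 0.10 and Orm1, an acute phase gene, by 1.61 ± 0.29.

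**Figure D1:**
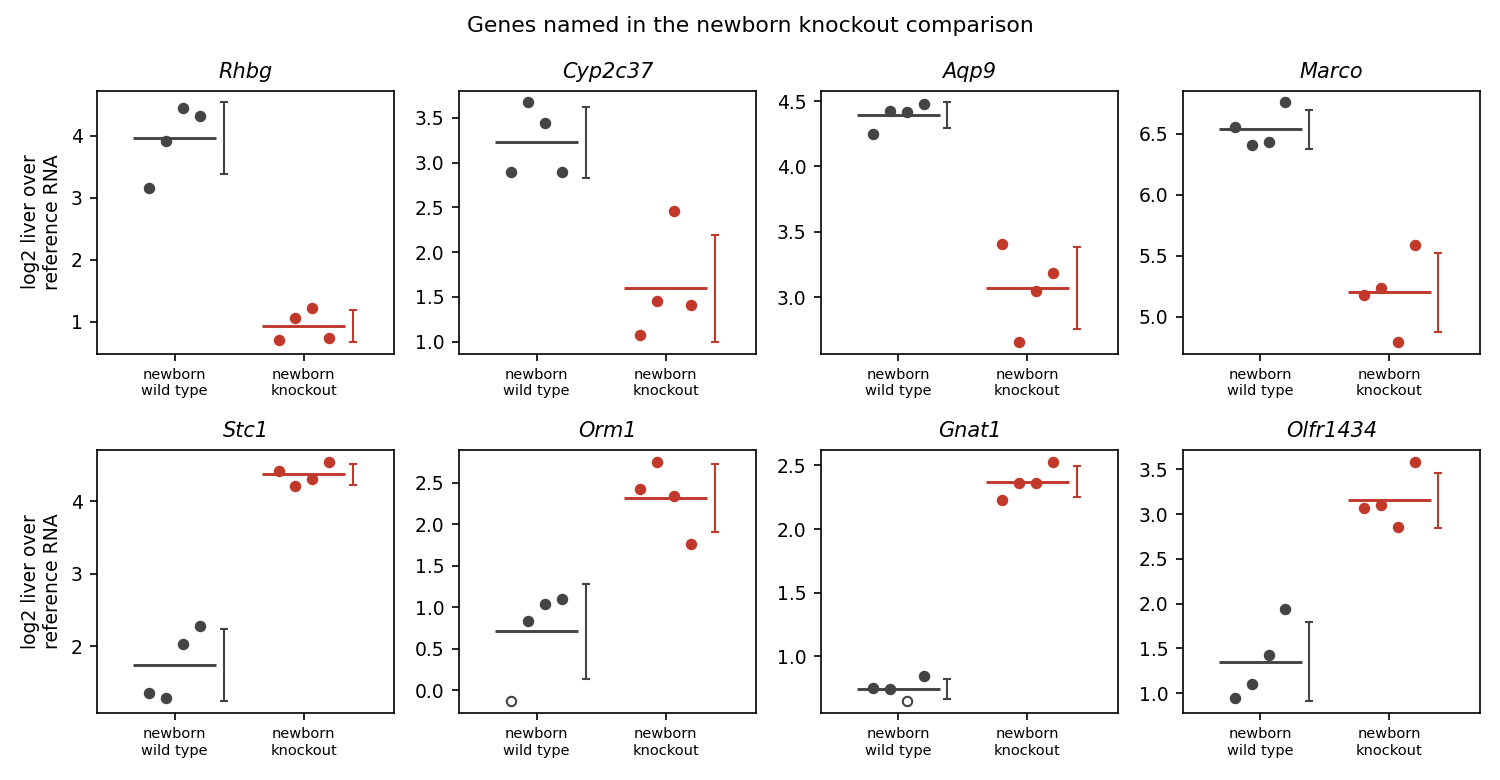
Log2 ratio of liver over reference RNA (vertical axis) of 8 genes in newborn wild-type and knockout livers, 1 point per array (filled where the probe was well above background, open where it was not), with the group mean as a line and its SD as a bar. Rhbg, Cyp2c37, Aqp9 and Marco lay lower in all 4 knockouts than in all 4 wild types, and Stc1, Orm1, Gnat1 and Olfr1434 lay higher, Stc1 at a mean of 4.37 against 1.74.

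In all, limma called 257 of 17153 genes in newborns, 198 higher and 59 lower in the knockout, of which 86 changed at least 2-fold. The ranges of the groups were separate for each of the 257. Chance gives this for 2.86% of unselected genes, but the 257 were picked for their difference, so it adds no support. The reference channel alone, which holds the same RNA on every array, differed between the groups in 2402 genes, 1638 of them higher on knockout arrays. With wild types on one slide and knockouts on another, slide and genotype cannot be told apart here. At an unadjusted p under 0.05, 2300 genes passed. With the local backgrounds marked as outliers kept, limma called no gene. The count was 23 with a filter on both channels, 110 with median centring, 909 with array weights and 1061 with the sample channel alone, and with the processed signals of Feature Extraction 270 genes were higher and 183 lower. Without wild type 1 and knockouts 1 and 4, which lay far along the first principal component, an alternative chosen after seeing the data, 72 were higher and 86 lower, and 81 of the 257 kept their call. The count was 433 without wild type 1, 72 without wild type 2, 66 without wild type 3 and 124 without wild type 4, and 132, 166, 76 and 80 without knockout 1, 2, 3 and 4. Of 24 called genes taken by the naming rule, 14 passed with each array left out, among them Rhbg, Stc1, Aqp9, Slc17a2, Marco, Gnat1, Olfr1434 and Vmn1r63. The calls of Slco1b2, Cyp2c37, Orm1, Hsd3b7, Gulo, Fcna and Csf1r ended with 5, 6, 6, 6, 7, 7 and 8 of the 8 arrays left out in turn.

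In livers of fasted adults labelled knockout, 5 of 17 tested Wnt target genes and 7 of 20 tested genes of the cells around the central vein were lower than in controls. Glul, which encodes glutamine synthetase, the classic marker of the innermost hepatocytes, fell from 4.54 ± 0.51 to 1.60 ± 0.58 (SD, n = 4 each), a log2 change of -2.94 ± 0.31 (SE, adjusted p = 0.000344) and 7.68-fold. Oat, the gene of ornithine aminotransferase, fell by 3.86 ± 0.23 (adjusted p = 1.03e-06) and Slc1a2, a glutamate transporter gene, by 3.90 ± 0.18 (adjusted p = 2.62e-07). Lhpp, which encodes a phosphatase, fell by 4.33 ± 0.23 (adjusted p = 4.46e-07), 20.2-fold. The Wnt target genes Sp5 and Lgr5 were well above background on all 4 control arrays and on no knockout array. They were at least 14.5-fold and at least 5.63-fold lower (adjusted p = 3.63e-07 and 0.000507). Over the alternatives their log2 changes ran from -7.26 to -2.61 and from -6.29 to -1.35, in part smaller than these bounds.

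Of 17 tested Wnt target genes 5 fell and none rose, and 8 fell and 1 rose when adjusted over the list alone. Beside Sp5 and Lgr5, Tbx3 fell by 3.77 ± 0.42 and Tnfrsf19 by 1.96 ± 0.17. Of 20 pericentral hepatocyte genes 7 fell and none rose, and 8 fell when adjusted over the list alone, among them Slc13a3, well above background on all 4 control arrays and on no knockout array. The lists share Lgr5, Tbx3 and Axin2. Both were lower by camera (adjusted p = 2.29e-05 for Wnt targets and 1.77e-11 for pericentral genes), also with an estimated correlation (adjusted p = 0.0482 for each). Their median changes were -0.28 and -0.43. Slide as a block cannot move these medians, since each slide held as many knockouts as controls. The medians were -0.23 and -0.58 on slide 3 and -0.33 and -0.21 on slide 4. Other genes with large falls were Aldh3a2, a fatty aldehyde dehydrogenase gene (-3.26 ± 0.19), and Ces2b, a carboxylesterase gene (-3.15 ± 0.26). Cyp2c38, a cytochrome P450 gene, was at least 8.30-fold lower, with log2 changes of -7.06 to -1.35 over the alternatives. Pparg, a regulator of lipid storage, fell by 2.25 ± 0.25 and the lipoprotein receptor gene Vldlr by 1.85 ± 0.17.

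The largest rises were of the cytochrome P450 genes Cyp2b9 (4.18 ± 0.68, adjusted p = 0.0125), Cyp2b10 (3.72 ± 0.47, adjusted p = 0.00175, well above background on all 4 knockout arrays and 1 control array) and Cyp2b13 (3.58 ± 0.67, adjusted p = 0.0338). These 3 were the only members of 12 tested female-biased liver genes to rise, while 5 rose when adjusted over the list alone (camera adjusted p = 0.000126, and adjusted p = 0.156 with an estimated correlation). Y-linked genes without Xist were well above background on each of the 8 fasted arrays. Cdkn1a, which encodes the cell cycle inhibitor p21, rose by 1.71 ± 0.26 and Bdh2 by 0.92 ± 0.12. Of 24 genes of cholesterol synthesis 1 fell, Nsdhl (-1.08 ± 0.21, adjusted p = 0.0466), 7 fell when adjusted over the list alone, and 22 lay below 0, with Mvk at -0.75 ± 0.17 (adjusted p = 0.0968). Their camera adjusted p was 5.55e-08, and adjusted p = 0.569 with an estimated correlation. None of 22 immediate early and stress genes passed in limma over all genes, 6 rose when adjusted over the list alone, and 20 lay above 0, with Mt2 at 3.33 ± 0.82 (adjusted p = 0.121). Their camera adjusted p was 2.72e-09, and adjusted p = 0.231 with an estimated correlation. Beside them, 11 pancreas and fat markers had a median change of 0.88, and none passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0116, and adjusted p = 0.653 with an estimated correlation). On the second principal component fasted knockouts 1 and 2 lay at -39.7 and -36.3, and fasted knockouts 3 and 4 at -2.87 and 1.78. The 17 Kupffer cell markers had a median change of 0.31, none passed over all genes or when adjusted over the list alone, and 14 lay above 0 (camera adjusted p = 0.00918, and adjusted p = 0.653 with an estimated correlation). Of 10 neutrophil and myeloid precursor markers 9 lay above 0 with a median of 0.33, and none passed over all genes or when adjusted over the list alone (camera adjusted p = 0.0487, and adjusted p = 0.653 with an estimated correlation). The medians of the female-biased, cholesterol, immediate early, pancreas and fat, Kupffer and neutrophil lists were 0.39, -0.41, 0.72, 0.88, 0.31 and 0.33. By the equal numbers on each slide, a slide block leaves these medians as they are. They were 0.28, -0.34, 0.95, 1.25, 0.25 and 0.46 on slide 3, and 0.63, -0.57, 0.24, 0.44, 0.16 and -0.02 on slide 4.

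In all, limma called 82 of 17162 genes in fasted adults, 19 higher and 63 lower in the knockout, of which 62 changed at least 2-fold and 80 had separate ranges. Chance gives separate ranges for 2.86% of unselected genes, but the 82 were picked for their difference, so this adds no support. With slide as a block the count was 130, 41 higher and 89 lower. Within slide 3 it was 111 and within slide 4, with 4 arrays as well, it was 0. With the local backgrounds kept it was 149, 120 higher and 29 lower, and without fasted knockout 4 it was 138. The calls of Cyp2b9 ended without fasted control 2 and without fasted knockout 1, that of Cyp2b13 with 7 and that of Nsdhl with 7 of the 8 arrays left out in turn. All falls named here except that of Nsdhl passed with each array left out.

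In livers of fed adults labelled knockout, 32 genes were lower, 22 of which were also lower in fasted adults. Lhpp fell by 4.33 ± 0.27 (SE, adjusted p = 4.13e-06), from 3.09 ± 0.37 to -1.24 ± 0.12 (SD, n = 3 each). Oat fell by 3.89 ± 0.26 (adjusted p = 9.30e-06), Glul by 3.82 ± 0.35 (adjusted p = 0.000155) and Ces2b by 3.10 ± 0.30 (adjusted p = 0.000212), with Ces2b well above background on 1 knockout array. Slc1a2, Vldlr and Tnfrsf19 were on no knockout array well above background, and Tnfrsf19 was so on 2 of 3 control arrays. They were at least 6.44-fold, at least 5.86-fold and at least 4.39-fold lower. Over the alternatives the log2 changes of Slc1a2 and Vldlr ran from -4.99 to -1.73 and from -4.10 to -2.01, in part smaller than these bounds. Sp5 was at least 1.81-fold lower, Pparg fell by 2.41 ± 0.29 and Aldh3a2 by 2.35 ± 0.22. Cyp4a14, an enzyme gene of fatty acid hydroxylation, fell by 2.03 ± 0.28 (adjusted p = 0.00597).

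Of 17 Wnt target genes 2 fell, and 4 when adjusted over the list alone. Of 20 pericentral genes 3 fell, and 7 when adjusted over the list alone. Both lists were lower by camera (adjusted p = 1.93e-06 and 7.98e-12), also with an estimated correlation (adjusted p = 0.0295 and 0.0329). Periportal hepatocyte genes, those of the opposite side of the lobule, stood higher. Of 21 tested, 1 rose, Etnppl (1.27 ± 0.20, adjusted p = 0.0172), 11 rose when adjusted over the list alone, and 19 lay above 0 (camera adjusted p = 2.12e-13, and adjusted p = 0.0329 with an estimated correlation). Hal, the gene of histidase, stood at 0.53 ± 0.10 (adjusted p = 0.0625) and Cps1, the gene of the first urea cycle enzyme, at 0.95 ± 0.18 (adjusted p = 0.0684). With slide as a block the median changes of the Wnt target, pericentral and periportal lists were -0.29, -0.33 and 0.33. They were -0.22, -0.23 and 0.38 on slide 5, and -0.30, -0.55 and 0.27 on slide 6. In fasted knockouts the periportal list did not pass, with a median of 0.06 and 11 of 21 above 0 (camera adjusted p = 0.3115, and adjusted p = 0.844 with an estimated correlation).

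None of 25 genes of the urea cycle and amino acid catabolism, a list that shares Cps1, Hal and others with the periportal one, passed over all genes in limma. When adjusted over the list alone 9 rose (camera adjusted p = 7.98e-12, and adjusted p = 0.0847 with an estimated correlation), with Ass1 at 0.69 ± 0.15 (adjusted p = 0.117). None of 23 acute phase genes passed, and 6 rose when adjusted over the list alone (camera adjusted p = 2.34e-11, and adjusted p = 0.134 with an estimated correlation), with Orm2 at 0.81 ± 0.18 (adjusted p = 0.121). All 17 Kupffer cell markers lay above 0 with a median of 0.47, none passed over all genes, and 7 rose when adjusted over the list alone (camera adjusted p = 1.46e-08, and adjusted p = 0.215 with an estimated correlation). Of 19 liver endothelial markers 18 lay above 0 with a median of 0.28, and none passed over all genes or when adjusted over the list alone (camera adjusted p = 0.000161, and adjusted p = 0.291 with an estimated correlation). Of 10 erythroid markers 8 lay above 0 with a median of 0.29, none passed over all genes, and 1 rose and 1 fell when adjusted over the list alone (camera adjusted p = 0.0217, 0.0551 with slide as a block, and adjusted p = 0.281 with an estimated correlation). Of 12 cholangiocyte markers 2 lay above 0, and the list did not pass (camera adjusted p = 0.191). With slide as a block the medians of the urea cycle, acute phase, Kupffer, endothelial and erythroid lists were 0.31, 0.28, 0.36, 0.26 and 0.24. They were 0.31, 0.36, 0.56, 0.41 and 0.33 on slide 5, and 0.28, 0.15, 0.24, 0.03 and 0.12 on slide 6.

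In all, limma called 37 of 17162 genes in fed adults, 5 higher and 32 lower, of which 33 changed at least 2-fold. All 37 had separate ranges, which chance gives for 10% of unselected genes at 3 against 3, but the 37 were picked for their difference. With slide as a block 16 were higher and 33 lower. Within slide 5 and within slide 6, each with 3 arrays, limma called no gene, while 1227 passed an unadjusted p under 0.05 with both slides together. With median centring no gene was higher and 32 were lower. The count was 22 with only these 2 groups in the fit, 11 with the local backgrounds kept, all lower, 68 without fed knockout 1 and 99 without fed knockout 3. The call of Etnppl ended with 4 of the 6 arrays left out in turn, while the falls named here passed with each array left out.

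**Figure D2:**
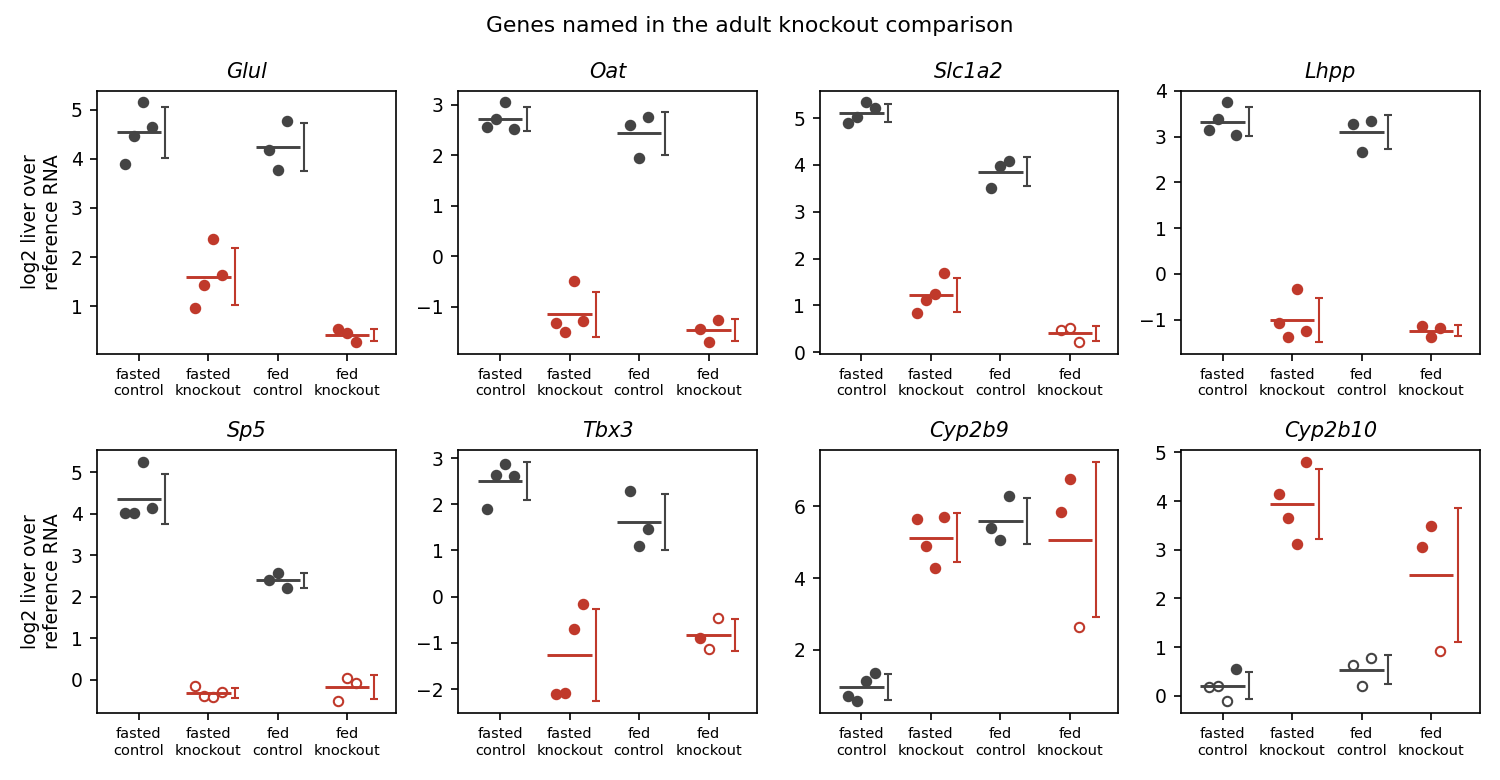
Log2 ratio of liver over reference RNA (vertical axis) of 8 genes in the 4 adult groups, 1 point per array (filled where the probe was well above background, open where it was not), with the group mean as a line and its SD as a bar. Glul, Oat, Slc1a2 and Lhpp lay lower in every knockout than in every control of the same feeding state, Glul at means of 1.60 against 4.54 fasted and 0.42 against 4.24 fed, and Cyp2b9 was low in fasted controls at a mean of 0.95.

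Of the 63 genes lower in fasted and the 32 lower in fed adult knockouts, 22 were shared, where independent lists would share 0.117 (two-sided Fisher's exact test, p = 2.62e-48). That test takes genes as independent, and both comparisons use the same estimate of each gene's spread, so its p overstates the evidence. The shared falls include Sp5, Lhpp, Slc1a2, Oat, Aldh3a2, Ces2b, Glul, Pparg, Tnfrsf19 and Vldlr. The only shared rise was that of Sdsl, which encodes a serine dehydratase-like protein, at 0.75 fasted and 0.86 fed, and its fed call ended without fed control 2, without fed control 3 and with slide as a block (adjusted p = 0.0613, 0.0522 and 0.0537). No gene was called in opposite directions. Across all 17162 genes, which are not independent replicates, the knockout changes in fasted and fed adults correlated weakly (Pearson r = 0.241, Spearman rho = 0.0771), and across the 96 genes called in either state r was 0.753. Newborn and fasted adult knockout changes correlated at r = 0.103 and rho = 0.0720 across 15863 genes, with 1 shared fall and 1 shared rise against 0.173 and 0.126 for independent lists. With the local backgrounds kept, that r was -0.146.

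**Figure D3:**
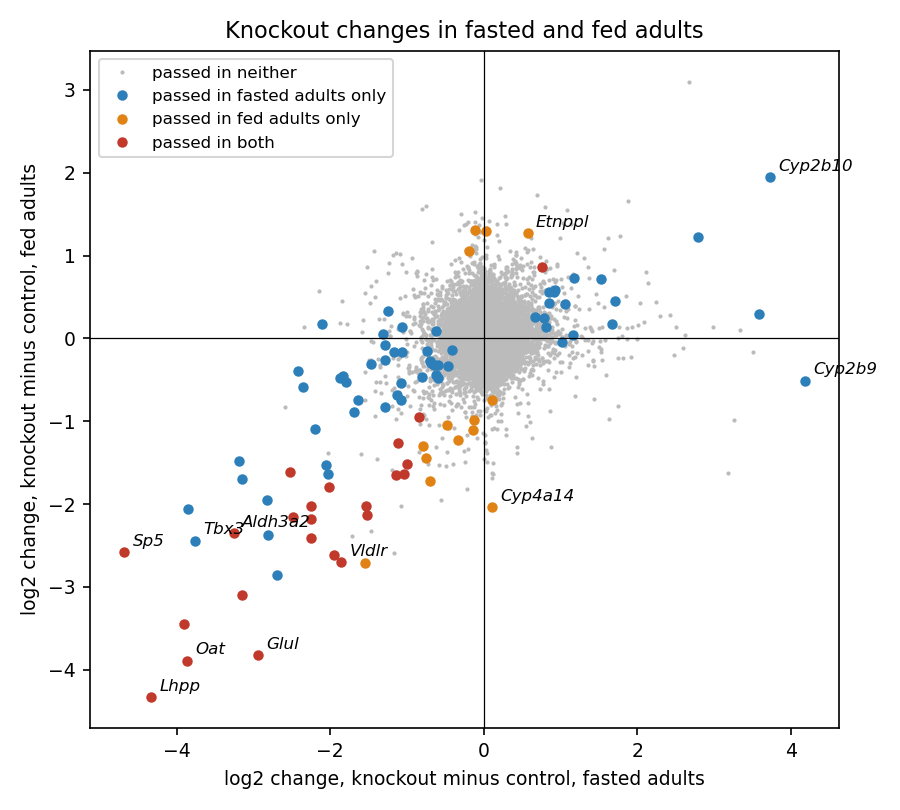
Log2 change between knockout and control in fasted adults (horizontal axis) against that in fed adults (vertical axis), 1 point per gene, coloured by the comparison in which it passed an adjusted p of 0.05. The 22 genes that fell in both, among them Lhpp at -4.33 in each, lie in the lower left, while Cyp2b9 lies at 4.18 in fasted adults.

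Livers of adults fasted for 24 h differed from those of fed adults, scanned on another day, in a large part of the transcriptome in both genotypes, with genes of the synthesis of fat and cholesterol among the falls. In controls, Fasn, the gene of fatty acid synthase, was lower in fasted than in fed livers by a log2 change of -2.79 ± 0.42 (SE, adjusted p = 0.000362) and Srebf1, which activates such genes, by -2.52 ± 0.26 (adjusted p = 2.91e-05). In knockouts these changes were -3.11 ± 0.42 and -2.63 ± 0.26. The acyl-CoA thioesterase gene Acot4 was higher in fasted livers, by 3.40 ± 0.38 in controls and 3.06 ± 0.38 in knockouts. Insig1, a sensor of sterols, fell by 1.76 ± 0.27 in controls and by 2.58 ± 0.27 in knockouts, and Nsdhl by 1.74 ± 0.23 and 2.29 ± 0.23. The endothelial receptor gene Kdr rose by 2.39 ± 0.18 and 1.72 ± 0.18.

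Of 24 genes of glycolysis and lipogenesis 11 fell in controls and 13 in knockouts, and none rose, while adjusted over the list alone 11 and 14 fell (camera adjusted p = 5.89e-05 and 1.50e-06, and adjusted p = 0.390 and 0.181 with an estimated correlation). Of 24 genes of cholesterol synthesis 13 and 18 fell, and adjusted over the list alone 15 and 19 (camera adjusted p = 1.78e-05 and 9.53e-09, and adjusted p = 0.435 and 0.394 with an estimated correlation). Of 25 genes of the urea cycle and amino acid catabolism 12 and 18 fell, with 12 and 19 adjusted over the list alone, and 1 rose in controls, or 2 adjusted over the list alone (camera adjusted p = 5.89e-05 and 2.70e-09, and adjusted p = 0.390 and 0.181 with an estimated correlation). They included Ass1 (-1.64 ± 0.14 and -2.15 ± 0.14) and Hal (-1.18 ± 0.09 and -1.56 ± 0.09). Of 21 periportal genes 11 and 12 fell and 4 and 1 rose (camera adjusted p = 0.00513 and 1.21e-06, and adjusted p = 0.435 and 0.181 with an estimated correlation), and adjusted over the list alone 11 and 13 fell and 4 and 2 rose. With an estimated correlation no list passed in either genotype.

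Of 19 liver endothelial markers 12 rose in each genotype, while 1 fell in controls and 4 in knockouts, with 13 rising in each and 3 and 4 falling when adjusted over the list alone (camera adjusted p = 0.000377 and 0.00328, and adjusted p = 0.390 and 0.456 with an estimated correlation). Of 17 Kupffer cell markers 8 rose in controls and none fell, with as many when adjusted over the list alone (camera adjusted p = 0.0340, and adjusted p = 0.71 with an estimated correlation). In knockouts 6 rose and 2 fell, with as many when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.219). Tie1 was at least 1.96-fold and at least 2.05-fold higher, well above background on no fed array. Genes of the acute phase were lower: 10 of 23 fell and 2 rose in controls, 13 fell and 1 rose in knockouts, and as many when adjusted over the list alone (camera adjusted p = 0.00522 and 3.79e-05, and adjusted p = 0.611 and 0.456 with an estimated correlation). Fgg, a fibrinogen gene, fell by 2.45 ± 0.18 and 2.69 ± 0.18. The largest fall in controls was that of Cyp2b9, at -4.64 ± 0.74 (adjusted p = 0.000483). In knockouts the largest rise was that of the metallothionein gene Mt2, at 5.06 ± 0.89 (adjusted p = 0.000960), and Cyp4a14 rose by 2.06 ± 0.26. The directions of Fgg in both genotypes, of Ass1 in controls and of Hal in knockouts turned with the sample channel alone, where the changes were 0.21, 0.20, 0.00596 and 0.0537, and that of Kdr in controls turned with the local backgrounds kept, at -0.22.

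**Figure D4:**
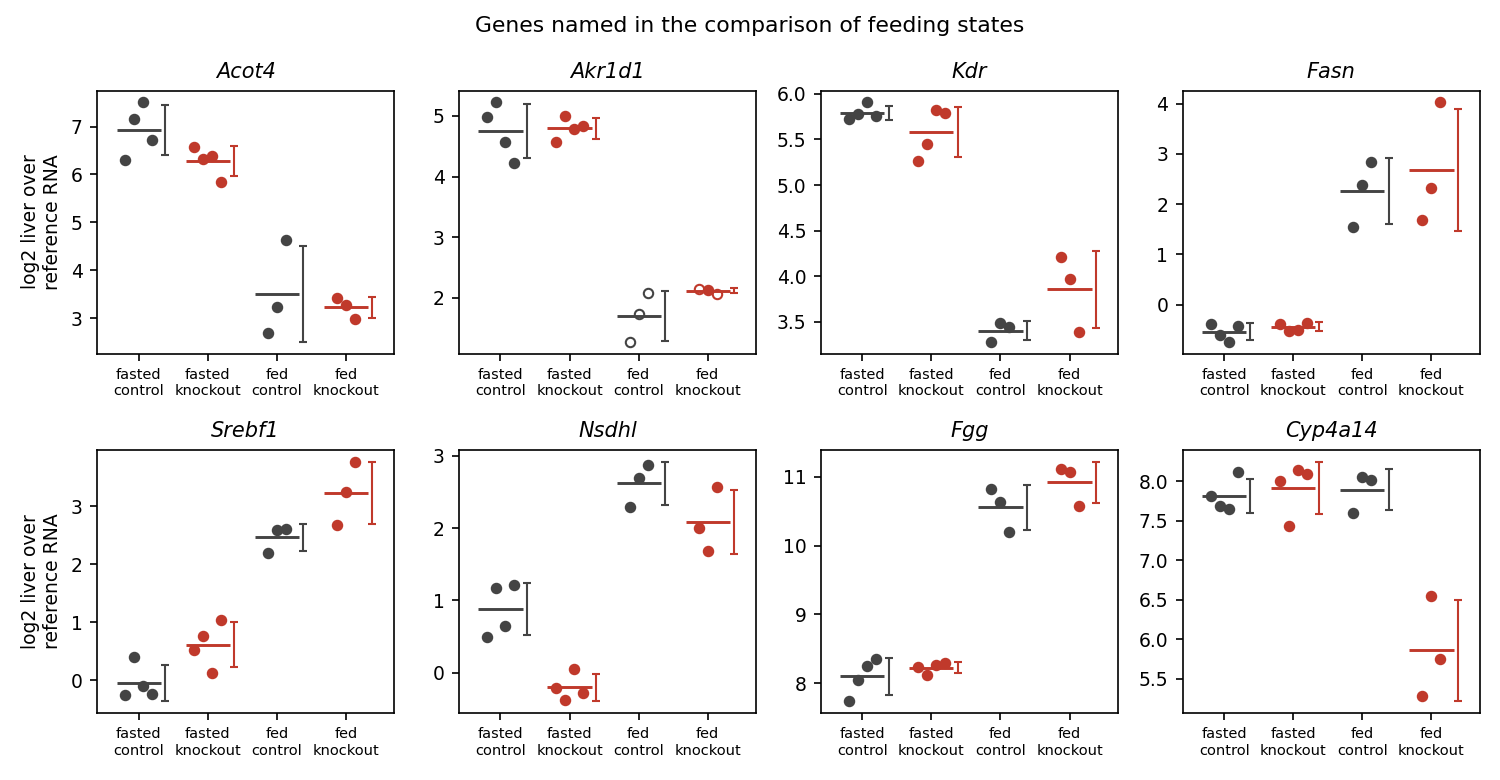
Log2 ratio of liver over reference RNA (vertical axis) of 8 genes in the 4 adult groups, 1 point per array (filled where the probe was well above background, open where it was not), with the group mean as a line and its SD as a bar. Acot4 and Kdr lay higher in fasted livers and Fasn, Srebf1, Nsdhl and Fgg in fed ones, Fgg at means of 10.55 in fed and 8.10 in fasted controls.

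In all, limma called 6321 of 17162 genes between fasted and fed controls, 3461 higher and 2860 lower in fasted livers, of which 1444 changed at least 2-fold. It called 6132 between fasted and fed knockouts, 3208 higher and 2924 lower, of which 1311 changed at least 2-fold. The fasting changes of controls and knockouts, which share no array, correlated at r = 0.814 and rho = 0.812 across genes. Both called 2237 rises and 2128 falls, against 647 and 487 for independent lists, and 4 genes passed in opposite directions. Fed and fasted livers were on different slides and scan days, and with slide as a random block 5767 and 5586 genes were called. The reference channel alone differed between fasted and fed arrays in 10143 genes in controls and 9509 in knockouts, so feeding state cannot be told apart from the day of the scan. With the processed signals of Feature Extraction the median of all genes moved to 0.41 in both genotypes, and 7364 genes were higher and 1711 lower in controls, 7161 higher and 1887 lower in knockouts. With median centring the medians were 0.26 and 0.30, and 6424 were higher and 2632 lower in controls, 7052 and 2064 in knockouts. With the Xist ratio as a covariate 65 genes were called in controls and 1233 in knockouts. Xist was well above background on no control array and on 1 knockout array, so these 2 counts say nothing about the sex of the adults. With the local backgrounds kept 3830 genes (1323 higher and 2507 lower) were called in controls and 3331 in knockouts.

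Whether the knockout changed the response to fasting was tested as an interaction of genotype and feeding state. The smallest adjusted p was that of Slc13a3, Cyp4a14 and Sp5. Their knockout change in fasted livers differed from that in fed livers by -1.76 ± 0.30, 2.14 ± 0.37 and -2.09 ± 0.36 (adjusted p = 0.359 each), and Slc13a3 and Sp5 were on no knockout array well above background. No gene passed in limma, and 1133 passed an unadjusted p under 0.05. With the processed signals of Feature Extraction 11 genes passed, with no background subtraction 1, and without fed knockout 3 there were 12. Of the 30 lists 13 passed in camera and none with an estimated correlation (smallest adjusted p = 0.326), led by immediate early and stress genes (median difference 0.71, 22 of 22 above 0, adjusted p = 4.44e-07) and periportal genes (median -0.39, adjusted p = 1.87e-06), in which no member passed over all genes and none and 2 when adjusted over the list alone.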

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

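The search for samples far from their group and the test of the interaction were set before the data were examined, and no test in this part was chosen after its result was seen. Among the genes and groups looked at, 165 groups of 4 arrays, 5 held an array far from the other 3, where chance gives 8.25. Sp5 read 5.26 in fasted control 3 and 4.02 to 4.14 in the other fasted controls, and Mvk read 0.22 there against 0.45 to 0.50. In fasted knockout 4 Cidec, a lipid droplet gene, read 3.84 against 7.06 to 7.27 in the other fasted knockouts, and Socs2, a feedback inhibitor of growth hormone signalling, read 0.51 against 2.87 to 3.29. Aldh18a1 read -3.48 in fasted knockout 1 against -4.00 to -3.97. With fewer such arrays than chance gives, no cause was looked for.

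The knockout change differed between fasted and fed adults for 13 gene lists in camera, each by a test of the interaction, and for no list with an estimated correlation (smallest adjusted p = 0.326). At the preset correlation it was higher in fasted than in fed livers for immediate early and stress genes (adjusted p = 4.44e-07), female-biased liver genes (0.00617), neutrophil and myeloid precursor markers (0.0104), pancreas and fat markers (0.0117), cholangiocyte markers (0.0236) and cell cycle genes (0.0386). It was lower in fasted than in fed livers for periportal genes (1.87e-06), the urea cycle and amino acid catabolism (4.08e-06), acute phase proteins (0.000108), erythroid markers (0.00299), cholesterol synthesis (0.00379), bile acid synthesis and transport (0.0117) and endothelial markers (0.0147). Among single genes none passed in limma and 1133 passed an unadjusted p under 0.05. With a real count of 0, all 100 drawn splits call as many by construction, up to 21 genes, so they decide nothing, and they do not test the lists. Feeding state went with slide and scan day, so a difference between the fasted and fed arrays cannot be told apart from one between days.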

How the results depend on the processing

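Chosen only after the results were seen were the local backgrounds kept as they were, the filter on the fed arrays and the newborn fit without 3 arrays. With the processed signals of Feature Extraction 453 newborn and 11 interaction genes passed and the interaction of Cps1 was 0.0530, and the deposited log ratios gave 452 and 11. Median centring gave 110 newborn genes. The sample channel alone gave 1061 newborn genes and turned the fasting changes of Ass1 (0.00596), Fgg (0.21), Apoa1 (0.61) and Gys2 (0.50) in controls and of Fgg (0.20), Trf (0.73) and Hal (0.0537) in knockouts, with Apoa1 and Trf past the threshold in the turned direction. The filter on both channels gave 23 newborn genes of 13744 tested, and of 7098 adult genes tested 41 in the fasted knockout, 23 in the fed knockout, 2745 by fasting in controls and 3289 in knockouts. Array weights gave 909 newborn genes. No background subtraction, the mean of the probes of a gene and the Xist ratio as a covariate gave 1 interaction gene each. The Xist ratio gave 65 and 1233 genes by fasting in controls and knockouts and turned Upk1a in controls (0.0400). Since Xist was well above background on no control array, its ratio does not stand for sex there. Slide as a block gave 130 genes in the fasted knockout, slide 4 alone gave 0, and slides 5 and 6 alone gave 0 in the fed knockout, with fewer arrays in each. Only the compared groups in the fit gave 22 fed genes. At least 2-fold left 86 newborn genes and 1444 and 1311 by fasting in controls and knockouts. Beyond fewer genes or arrays tested, the cause was not tested.

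With the local backgrounds kept, the counts were 0 in newborns, 149 in the fasted and 11 in the fed knockout, 3830 and 3331 by fasting in controls and knockouts, Kdr in controls was -0.22, the interaction of Cps1 was 0.17, and the correlations were -0.146 between newborn and fasted adult knockout changes and 0.589 between the fasting changes. The filter on the fed arrays gave 3380 and 3905 genes by fasting of 8863 tested, and a correlation of 0.334 between fasted and fed knockout changes. Without newborn wild type 1 and knockouts 1 and 4, which lay far along the first principal component, 158 newborn genes passed, 72 higher and 86 lower, and 81 of the 257 kept their call. With an estimated correlation 0, 2, 3, 0, 0 and 0 lists passed in newborn, fasted knockout, fed knockout, the fasting comparisons and the interaction, against 10, 11, 14, 13, 13 and 13.

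With each array left out in turn the counts were 66 to 433 in newborns, 58 to 138 in the fasted knockout, 30 to 99 in the fed knockout, 4847 to 5885 and 4958 to 5586 by fasting in controls and knockouts, and 0 to 12 for the interaction. The correlations were 0.194 to 0.287 between fasted and fed knockout changes, 0.0706 to 0.126 between newborn and fasted ones, and 0.766 to 0.836 between the fasting changes. Tcf7l2 in newborns passed with the sample channel alone (adjusted p = 0.0222), array weights (0.00968), the replicate number as a block (0.0355) and without wild type 1 (0.0152). Over all alternatives, the named called genes kept direction and call in 394 of 542 values in newborns, 569 of 707 and 294 of 390 in the fasted and fed knockout, and 674 of 737 and 629 of 654 by fasting in controls and knockouts, and the rest lost the call except the turned ones given above. Aquantile normalization leaves ratios as they are, so it moved nothing. The deviations of same-numbered arrays from their group means correlated at only -0.13 to 0.16 in adults, so replicate numbers do not pair those arrays. In newborns they correlated at 0.50, 0.35, 0.39 and -0.23 for replicates 1, 2, 3 and 4, so a pairing stays open there. With replicate numbers as a block 356, 63, 29, 5572, 5563 and 0 genes passed. Signal over background limits the fed arrays most.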

Other observations

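Tests chosen only after their result was seen in this part are the splits even over slides, that of dim spots with median centring, that of the sample channel alone for the fasting falls and the 3 for the adult falls. Some genes of glucose production were lower in fasted than in fed livers, which were scanned on another day. G6pc, which encodes the last enzyme of glucose release, fell by 0.80 ± 0.11 (SE) in controls and by 1.09 ± 0.11 in knockouts. Of 23 gluconeogenesis genes 8 fell and 2 rose in controls and 9 fell and 2 rose in knockouts, as many when adjusted over the list alone (camera adjusted p = 0.00989 and 0.0325, and adjusted p = 0.435 and 0.491 with an estimated correlation). Of 20 genes of bile acid synthesis and transport 11 fell and 3 rose in controls, and 12 fell and 2 rose in knockouts, with 11 and 12 falling and 4 and 3 rising when adjusted over the list alone (camera adjusted p = 0.0844 and 0.00552, and 0.482 in knockouts with an estimated correlation). Among the rises in controls were Akr1d1, at least 3.00-fold, and Cyp8b1, by 2.11 ± 0.30. Of 22 genes of lipoprotein metabolism 12 fell in each genotype, and 13 when adjusted over the list alone, with 2 rising in controls and 1 in knockouts (camera adjusted p = 5.89e-05 and 9.66e-06, and adjusted p = 0.308 and 0.181 with an estimated correlation). Apoa1 fell by 1.45 ± 0.12 in controls, but with the sample channel alone it passed in the opposite direction, at 0.61 (adjusted p = 0.0143).

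Splits of the same arrays into other groups of the same sizes were counted for each count of genes. In newborns the real split called 257 genes and the highest other split 223, that of wild types 1 and 4 and knockouts 1 and 4 against the rest. The real split was the only 1 of 35 to call as many, which is the smallest share that 35 splits can give. Chance is less likely by this but not excluded, since the highest other split came close and the comparisons were not adjusted for each other. In fasted adults the real split called 82 genes and was the only 1 of 35 to call as many. The highest other, slide 3 against slide 4, called 52. Among splits that ignore the slides this argues against chance, at the smallest share they can give. Of the 18 splits that part each slide evenly, the real one alone called as many, with 7 in the highest other, and these are too few for a share under 0.05. In fed adults 3 of 10 splits called as many as the real 37, with 55 in the highest other. These splits are too few for a share under 0.05. The split of slide 5 against slide 6 called 43, and with slide as a block genotype called 49. By fasting, the real split was the only 1 of 35 to call as many in controls (6321, highest other 991) and in knockouts (6132, highest other 1453). This argues against chance, though the slide and day of the scan follow the real split.

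Among newborns, 198 genes were higher in the knockout, with a median rise of 0.83. The reference channel of these genes read higher by a median of 0.28 on the knockout slide, which lowers the ratio and argues against the reference as the source of the rises. The 4289 genes with the lowest signal had a median change of 0.0288, which decides nothing, since loess centres the ratio at each signal level. With median centring it was 0.0250 (quartiles -0.10 to 0.15) against 0.59 for the 198, which were picked for their rise. That does not decide on a general lift of dim spots either. Median centring sets the median ratio of all spots, many of them dim, to the same value on each array. With the Xist ratio as a covariate 258 genes were higher and 238 of the 257 calls were kept. Xist and Y-linked genes were both well above background on 1 wild-type and 2 knockout arrays. The Xist ratio may therefore not sort the pups by sex, so this does not decide on sex as a source. A fault of a slide that touches single probes stays open and cannot be told apart from an effect of the genotype, since each genotype filled a slide.

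Between fasted and fed controls, 2860 genes were lower in fasted livers, with a median of -0.72. The reference channel of these genes read higher by a median of 0.26 on fasted arrays. That lies between the bounds set for and against the reference as the source, so it does not decide. For the 2924 falls in knockouts, with a median of -0.69, the reference read higher by a median of 0.35. By the bound set for controls, that size goes with the reference as a source. Of the 1042 falls in controls among the 4291 brightest genes, 56.2% were also lower with the sample channel alone, so a part made by the dye normalization cannot be told apart from feeding. The effect of fasting stays open beside both, since feeding state went with the day of the scan.

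In adults, 63 genes were lower in the fasted knockout. Of these, 22 also fell in the fed knockout, on other slides, other mice and another day, where independent lists share 0.117, which argues against a peculiarity of the fasted arrays for these. The other 41 had a median change of -0.47 on fed arrays, 36 of them below 0, against -1.29 on fasted ones, which leaves it open for them. With the processed values of the authors, made from the same scans, 63 of 63 were lower and 40, or 63.5%, were called. That argues against the replaced local backgrounds as the source for those 40 and leaves it open for the others. With the local backgrounds kept fewer genes were lower, as given above. Of 27 called genes taken by the naming rule, rises and falls together, 13 then lost the call and none turned. As a hypothesis, the 22 shared falls are consistent with an effect of the labelled genotype, though no lower Tcf7l2 was seen on these arrays.

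On the first principal component of the newborn arrays, 44.9% of the variance, wild type 1 lay at -36.4 and knockouts 1 and 4 at -27.7 and -33.6, with the other 5 at 14.6 to 23.9. On that of the adult arrays, 47.6%, fasted and fed arrays lay apart, and on the second, 11.2%, fasted knockouts 1 and 2 lay at -39.7 and -36.3. Of newborn wild types, 2 arrays showed Y-linked genes well above background, 1 Xist and 1 both, and of newborn knockouts 2 showed Y-linked genes and 2 both. All adult arrays showed Y-linked genes without Xist, except 1 fed knockout array with both.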
